A study of Zea mays with 6 samples.

How the data were processed

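Messenger RNA of whole maize kernels (Zea mays, inbred line KN5585) was sequenced at 10 days after pollination. The labels put 3 libraries in a ZmSUS1 transgenic group and 3 in a non-transgenic control group, and the series text calls the 3 libraries of a group biological replicates. Groups and replicate numbers were taken from the sample titles.

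The authors deposited 1 table per library with FPKM values (fragments scaled to gene length and to the mapped fragments of a library), per the file headers, rounded to 2 decimals. The aligner, the counting tool, the genome build and the gene annotation are not given in the sources used here. DESeq2 is named in the submitters' processing notes, without a version or a role. Each table lists the same 33051 gene IDs, each above 0 in at least 1 library; genes at 0 throughout are not listed. FPKM divides by the total of a library, so a gene also moves when a few very abundant genes take a larger or smaller part of that total. An FPKM of exactly 0 is given here as listed at 0.

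Total fragment counts are not given, and no counting interval or detection floor was computed. The relative depth was estimated from genes at 1 to 3 FPKM, whose values move in steps of single fragments. The most frequent ratio of such values to control library 1 gave relative depths of 1 for control 1, 0.997 for controls 2 and 3, and 1.01, 1.01 and 1.00 for transgenic 1 to 3. Only ratios close to 1 were searched, so a larger difference in depth could not have been found.

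Gene names came from a RefSeq gene table for assembly Zm-B73-REFERENCE-NAM-5.0. It matched 199 organelle IDs (94 plastid and 105 mitochondrial) by locus tag and 0 of the 32852 nuclear IDs, which are reported as the files give them. The ID of SUS1, Zm00001d047253, is stated in the series text. Because the build behind the files is not stated, no coordinates are given. The 22 gene lists fixed before the data were examined (among them starch synthesis, zeins, sucrose use, endosperm, embryo and aleurone markers and stress genes) therefore had 1 nameable tested member, SUS1. No list reached the minimum of 3 members, and the list tests (limma camera and fry) were not run on them. They were run on the plastid and the mitochondrial genes, a choice made after seeing the data.

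From the deposited FPKM values, log2(FPKM + 1) was computed for the 20514 genes with a mean of at least 1 FPKM over the 6 libraries. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated variance with a mean trend, all 6 libraries, no covariate, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Single values were compared with an exact permutation test of 3 against 3 libraries, which cannot give a 2-sided p below 0.1. The model was tested on simulated data made from the means and residual spread of the 20514 genes with 200 changed genes. It recovered 40.3% of the 1.5-fold, 82.1% of the 2-fold and 93.9% of the 4-fold changes, and 4.64% of its calls were false. The simulation held far fewer changed genes than the 3907 called in the data, so 4.64% is not an estimate for those calls.

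Both groups carry replicate numbers 1 to 3. The deviations of same-numbered libraries from their group means correlated at 0.13, 0.12 and 0.33 across genes. All were over 0.1, so the numbers were taken to pair the libraries. However, control 2 and transgenic 1 correlated at 0.105, also over 0.1, and control 1 and transgenic 2 at 0.0847. The values set number 3 apart but do not decide how numbers 1 and 2 pair. Pairing by number comes from the values, not from a label. The fit with the number as a block was run as an alternative.

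The rule for named genes, fixed before the data were examined, took SUS1 and all sucrose synthases. It added the 10 largest rises and the 10 largest falls with a name, an adjusted p under 0.05, an absolute log2 fold change of at least 1 and groups that do not overlap. It also took up to 4 members of each list, every starch synthesis gene at a mean of at least 10 FPKM, and the 2 largest rises and 2 largest falls without a name. Of the 359 genes past the criteria, 0 had a name, so only the 4 unnamed IDs and SUS1 could be reported by this rule. The 4 organelle genes with the smallest p were added after seeing the data. Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, and 5 FPKM), 3 other scalings, other variance priors, sample weights, the replicate block, a stricter threshold and leaving out libraries. Among the tested genes, 117 in 56 sets had values identical to another gene in all 6 libraries, as near-identical copies sharing reads would. 35 of these 117 were among the calls and remain uncertain.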

Results

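The 6 libraries held 3 kernel samples labelled transgenic and 3 labelled control. Summed FPKM ranged from 1359751 to 1378937 per library. Between 28449 and 29052 genes were above 0 and between 20147 and 20776 genes reached 1 FPKM. Within a group, log2(FPKM + 1) values of 2 libraries correlated across genes at 0.982 to 0.988, and between the groups at 0.965 to 0.973. The first principal component held 53.1% of the variance and separated the groups. The second held 19.0% and set replicate 3 of both groups apart from replicates 1 and 2.

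**Figure D1:**
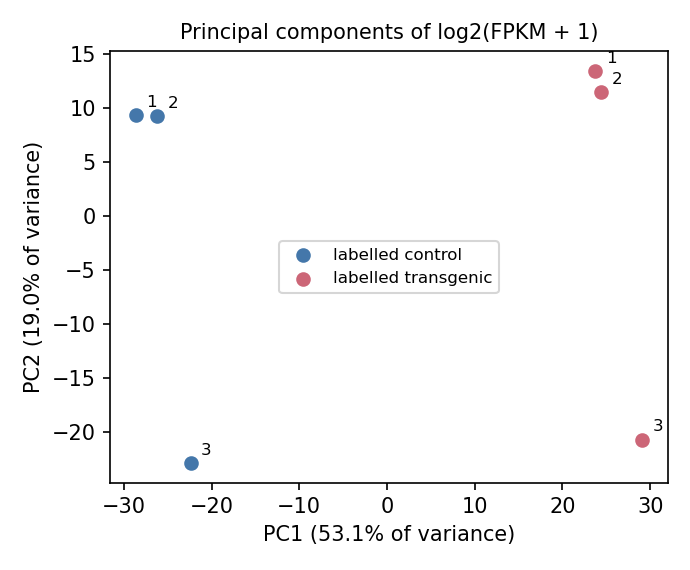
Scores of the 6 libraries on the first (x axis) and second (y axis) principal component of log2(FPKM + 1), in arbitrary units, with the share of variance on each axis; each point is 1 library with its replicate number. The groups part along the first component, and replicate 3 of both groups scores -22.9 and -20.7 on the second.

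The series was made to study overexpression of SUS1, which encodes a sucrose synthase, an enzyme that cleaves sucrose to fructose and UDP-glucose. SUS1 (Zm00001d047253) fell in the libraries labelled transgenic. It stood at 215 ± 5.58 FPKM (SD, n = 3) in the libraries labelled control and at 155 ± 5.37 FPKM (SD, n = 3) in those labelled transgenic, which is 28.1% lower. The 3 values labelled control were 214, 210 and 221 FPKM, and the 3 labelled transgenic were 155, 149 and 160 FPKM. The log2 fold change was -0.47 with a standard error of 0.050 (limma, adjusted p = 0.000759), and 3 of 3 transgenic libraries lay below every control. The exact permutation test gave p = 0.1, the smallest it can give. This direction goes against the overexpression that the series was made to study, so the groups are named by their labels throughout. SUS1 ranked 331 among all genes by mean FPKM.

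**Figure D2:**
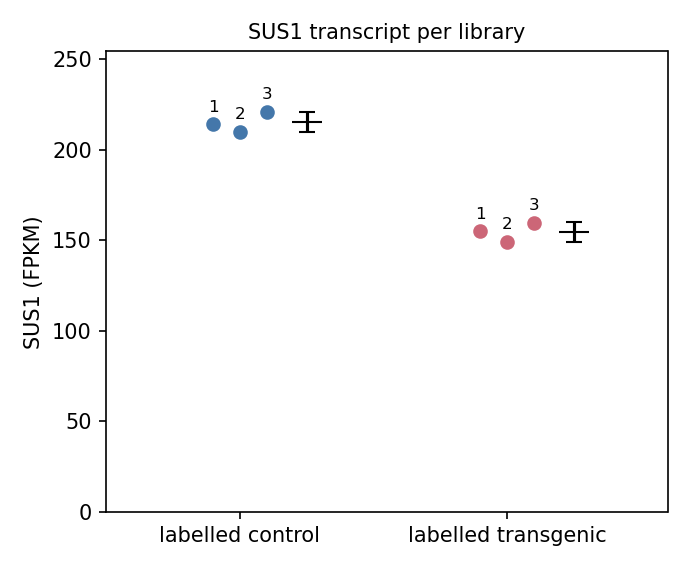
SUS1 transcript level in FPKM (y axis, from 0) in each library of the 2 labelled groups (x axis); points are libraries with their replicate numbers, and the black bars are group means with SD (n = 3). The 3 libraries labelled transgenic lie between 149 and 160 FPKM, below the 3 labelled control at 210 to 221 FPKM.

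Across all genes, the comparison asked which transcripts differed between the transgenic kernels and their non-transgenic control. Of 20514 genes tested, 3907 (19.0%) passed the limma test at an adjusted p of 0.05, 591 higher and 3316 lower in the libraries labelled transgenic. The median absolute log2 fold change of these calls was 0.48. A log2 fold change of at least 1 was reached by 80 of the genes that rose and 280 of those that fell. With a pseudocount of 0.1 these were 118 and 484, with FPKM rescaled to the sum without the 20 most abundant genes 106 and 202, and among genes at a mean of at least 5 FPKM 27 and 128. The median gene of all tested was lower by a log2 fold change of -0.13, and the balance of higher and lower calls depended on this shift. With median-ratio rescaling, which moved the median to -0.0041, 1217 genes rose and 1537 fell. With quantile normalization 1369 rose and 1440 fell, and with FPKM rescaled to the sum without the 20 most abundant genes 1405 rose and 1398 fell. As calls in the same direction under all 3 rescalings, 589 of the genes that rose and 1348 of those that fell were kept. All 3 moved the median gene upward, which favours rises and works against falls. The kept counts are therefore not a like test of the directions. Relative to the median gene, SUS1 was at 0.785 of its control level, and its log2 fold change with median-ratio rescaling was -0.33 with a standard error of 0.0528 (limma, adjusted p = 0.00544). In 7989 genes (38.9%) the values of the 2 groups did not overlap, and in 6951 (33.9%) with median-ratio rescaling. Chance gives 10% for exchangeable libraries, and the 9 other splits of these libraries gave 5.10% to 9.25%. Those splits mix the 2 labelled groups, so a group difference widens the spread within each side and lowers their share. The number of calls was lower when any single library was left out. It was 2331 without control 1, 2345 without control 2 and 3316 without control 3. Without transgenic 1, 2 and 3 it was 2841, 2470 and 2944. Without replicate 3 of both groups it was 2889, of which 419 rose and 2470 fell. All these fits held fewer samples, so a lower count does not by itself mark a library as influential.

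**Figure D3:**
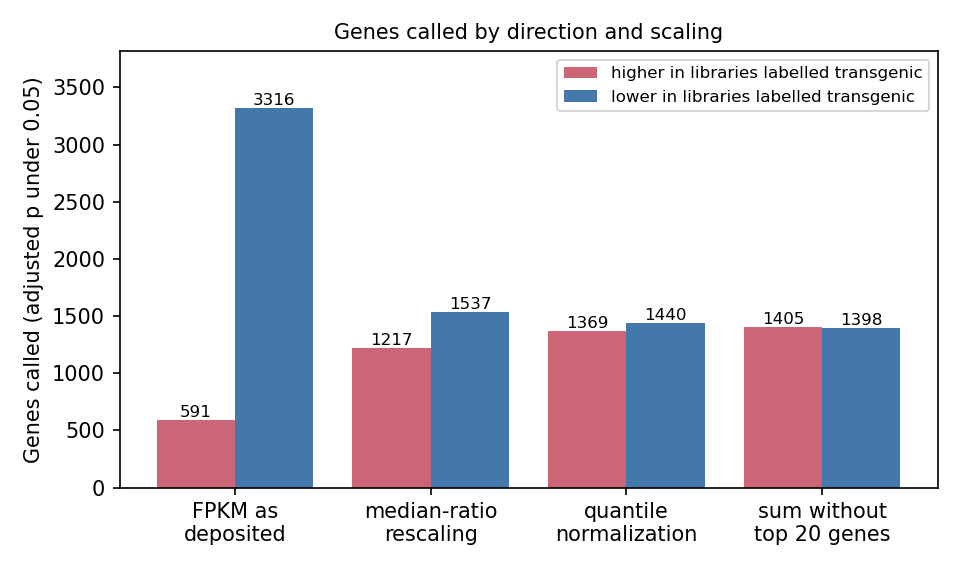
Number of genes called by limma at an adjusted p under 0.05 (y axis) that were higher or lower in the libraries labelled transgenic, for the deposited FPKM and 3 rescalings (x axis). The deposited values give 591 higher and 3316 lower, and the rescalings give between 1217 and 1405 higher and between 1398 and 1537 lower.

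The largest falls and rises on the log2(FPKM + 1) scale were in nuclear genes that the files give by ID alone. Zm00001d043988 fell from 81.2 ± 6.42 FPKM to 1.93 ± 0.245 FPKM (SD, n = 3 each), so its mean FPKM was 42.0-fold lower in the libraries labelled transgenic. Its log2 fold change on the log2(FPKM + 1) scale was -4.81 (limma, adjusted p = 3.14e-07). Zm00001d031158 fell from 19.2 ± 2.65 FPKM to 0.210 ± 0.0693 FPKM (SD, n = 3 each), with a log2 fold change of -4.06 (limma, adjusted p = 3.75e-06). Zm00001d032128 was listed at 0, 0 and 0.23 FPKM in the libraries labelled control and rose to 9.77, 7.02 and 4.96 FPKM in those labelled transgenic (limma, adjusted p = 0.000157). Zm00001d049254 was listed at 0 in all 3 libraries labelled control and rose to 4.64, 3.99 and 5.55 FPKM in the others (limma, adjusted p = 4.68e-05). All 4 kept their direction and their call under the 3 rescalings and under both smaller pseudocounts. Size and order depend on the pseudocount. At 0.1 the log2 fold change was -5.33 for Zm00001d043988, then 11th among the falls, and -5.98 for Zm00001d031158, then 5th, while the 2 rises changed places at 5.57 for Zm00001d032128 and 5.58 for Zm00001d049254. What these 4 genes encode is not given in the sources used here.

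The most abundant transcripts took a larger part of the libraries labelled transgenic. The 20 most abundant genes, all nuclear and given by ID alone, held 58.2 ± 1.21% of the summed FPKM in the libraries labelled control and 62.9 ± 0.727% in those labelled transgenic (SD, n = 3 each). The shares did not overlap (57.2% to 59.5% against 62.2% to 63.6%), and the exact permutation test gave p = 0.1, the smallest it can give. The 5 most abundant genes alone held 27.6 ± 0.437% and 29.98 ± 0.297% (SD, n = 3 each). Of the 20 genes, 4 rose and 0 fell by the limma test on deposited values, and 13 had a higher mean. Among the 4, Zm00001d048808, Zm00001d048810 and Zm00001d048816 lie within 10 ID numbers of each other, and other genes of the 20 also have nearby ID numbers. Such genes may not be independent, which limits all counts over the 20. With median-ratio rescaling 11 of the 20 rose and 0 fell, with the sum without these genes 12 rose and 0 fell, and with quantile normalization 2 rose and 1 fell. With the replicate number as a block 11 rose and 2 fell, without replicate 3 of both groups 8 rose and 1 fell, and leaving out single libraries left between 1 (without transgenic 2) and 6 (without control 3) that rose. All 20 had a mean above 10000 FPKM, and their median log2 fold change was 0.11. The median was -0.11 for the 12102 genes between 1 and 10 FPKM, -0.14 for the 7725 genes from 10 to 100, -0.11 for the 618 genes from 100 to 1000 and -0.15 for the 49 genes from 1000 to 10000. FPKM outside the 20 genes summed to 570180 ± 17900 in the libraries labelled control and 508010 ± 13400 in the others (SD, n = 3 each).

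**Figure D4:**
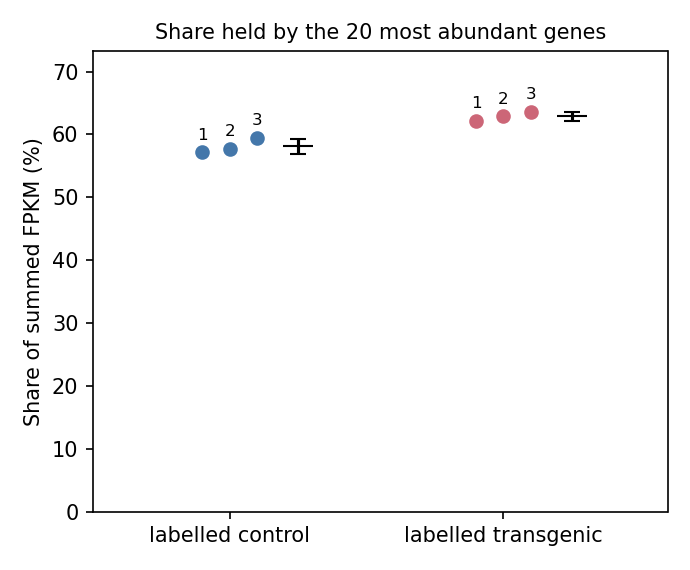
Share of the summed FPKM held by the 20 most abundant genes (y axis, percent, from 0) in each library of the 2 labelled groups (x axis); points are libraries with their replicate numbers, and the black bars are group means with SD (n = 3). The libraries labelled transgenic lie at 62.2% to 63.6% and those labelled control at 57.2% to 59.5%.

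Organelle genes were the only genes besides SUS1 that could be named. Their FPKM values were low in these messenger RNA libraries, and the amount of organelle RNA in the kernels was not measured. All 94 plastid IDs, tested or not, summed to 27.9 ± 2.60 FPKM in the libraries labelled control and 22.9 ± 2.52 FPKM in those labelled transgenic (exact permutation test, p = 0.2, n = 3 each). All 105 mitochondrial IDs, tested or not, summed to 58.1 ± 2.27 and 49.0 ± 3.09 FPKM (exact permutation test, p = 0.1, n = 3 each). This difference came from orf111-b, since the other mitochondrial genes summed to 37.5 ± 1.44 and 38.0 ± 4.99 FPKM (SD, n = 3 each). Of the 15 organelle genes tested, 1 passed, both over all genes and adjusted over the list alone. This was the mitochondrial open reading frame orf111-b (ZeamMp158), which fell from 20.5 ± 2.15 to 11.04 ± 2.15 FPKM (SD, n = 3 each), a log2 fold change of -0.85 with a standard error of 0.135 (limma, adjusted p = 0.00464). Its log2 fold change was -0.71 with median-ratio rescaling (limma, adjusted p = 0.0119). The plastid gene psbJ (ZemaCp037), for a small subunit of photosystem II, had 2.16 ± 0.725 and 0.953 ± 0.413 FPKM (SD, n = 3 each; limma, adjusted p = 0.0579). Its single values were low (1.44, 2.16 and 2.89 against 0.71, 1.43 and 0.72 FPKM) and moved in steps of about the smallest of them, so each rests on few fragments. With the replicate number as a block the psbJ difference passed at a limma adjusted p of 0.0450, and over its 17 alternatives the adjusted p ranged from 0.0423 to 0.248, with 3 passing. The plastid gene petA (ZemaCp036), for cytochrome f, had 1.73 ± 0.0896 and 1.07 ± 0.376 FPKM (SD, n = 3 each; limma, adjusted p = 0.111). The mitochondrial orf101-a (ZeamMp044) had 3.54 ± 0.662 and 4.63 ± 0.582 FPKM (SD, n = 3 each; limma, adjusted p = 0.158). As sets, neither the 5 plastid genes nor the 10 mitochondrial genes passed the test against the other genes (camera, adjusted p = 0.604 and 0.136 with the preset correlation, 0.648 and 0.383 with an estimated correlation). The median log2 fold change was -0.41 for the plastid set and 0.0073 for the mitochondrial set. fry gave an adjusted p of 0.172 and 0.944. The mitochondrial set holds orf99-b1 and orf99-b2, whose values were identical in all 6 libraries (log2 fold change 0.32 each), so the same values count more than once.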

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

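All alternatives were set before the data were examined, except leaving replicate 3 out of both groups, the leave-outs of the share held by the 20 most abundant genes and the organelle sets. SUS1 stayed lower and past the threshold under all 18 (log2 fold change from -0.50 to -0.31). The share of the 20 genes stayed higher when any of the 6 libraries was left out, and the shares of the top 5 and top 100 genes were also higher. Scaling moved the directions: 1217 higher and 1537 lower with median-ratio rescaling, 1369 and 1440 with quantile normalization, and 1405 and 1398 with the sum without the 20 most abundant genes, because these scalings remove the median shift. A log2 fold change of at least 1 left 360 calls (80 higher, 280 lower; 118 and 484 with a pseudocount of 0.1, 99 and 376 with 0.5, and 27 and 128 at a mean of at least 5 FPKM), and an adjusted p under 0.01 left 1591 (235 higher, 1356 lower). Leaving out single libraries gave 2331 to 3316 calls, 354 to 459 higher and 1931 to 2863 lower, with fewer samples in each fit. The replicate block gave 4469 calls (716 higher, 3753 lower), 3647 of them shared with the fit without it, and, of SUS1, the 4 unnamed IDs of the largest changes, orf111-b, psbJ, petA and orf101-a, changed the call of psbJ alone, which also passed without control 1 and without transgenic 2 but in none of its other 14 alternatives (adjusted p from 0.0423 to 0.248). The alternatives for the gene lists fixed in advance were not run, since no list had 3 nameable members. Depth limits low genes, whose values at 1 to 3 FPKM move in steps of single fragments.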

Other observations

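The tests of library depth, of exchanged labels and of neighbouring genes, and the comparison of replicate 3 with the other replicates, were chosen after their results had been seen.

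A small set of genes was present in one labelled group and near 0 in the other. In 9 genes the libraries labelled control averaged at least 5 FPKM while no library labelled transgenic exceeded 0.5 FPKM, and Zm00001d031158 was among them. The reverse held for 2 genes, Zm00001d032128 and Zm00001d048504, and the latter rests on 1 library, at 18.3 FPKM in transgenic 3 and listed at 0 in the other 5. In the 9 genes every library labelled control had at least 4.58 FPKM, and no library labelled transgenic exceeded 0.31 FPKM. The 11 genes compare with at most 3 in any other of the 10 splits of the 6 libraries. Those splits mix the 2 labelled groups, so a gene high in every library of 1 group cannot be near 0 on either side. Their counts therefore do not give the number expected from noise of low values, and 10 splits are too few for a share under 0.05. Of the 9 genes, 3 (Zm00001d024208, Zm00001d024210 and Zm00001d024211) lie within 10 ID numbers of each other and may not be independent. Genes called with a log2 fold change of at least 1 also tended to have nearby ID numbers. Of 352 such genes without an identical copy, 76 had another within 10 ID numbers, against a mean of 47.8 and a maximum of 85 in 10000 permutations (p = 0.001), and 33 of the 40 neighbouring pairs moved the same way, against a mean of 26.7 when the directions were permuted (permutation p = 0.018). IDs with nearby numbers are taken here to lie near each other in the genome, so a difference between the plants in some genome segments, or related genes lying side by side, may explain part of this pattern, and these were not told apart.

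SUS1 was lower, not higher, in the libraries labelled transgenic. Scaling by a few abundant genes does not account for it, since the log2 fold change was still -0.33 with a standard error of 0.0528 after median-ratio rescaling. A single mislabelled library or an exchanged pair is argued against by all tested genes other than SUS1, over which 0 of the 6 libraries correlated better with the other group than with their own. An exchange of the labels of the 2 groups as a whole, which would make SUS1 1.39-fold higher in the transgenic kernels, cannot be told apart from a true fall, because no other value in the files marks the transgene. A fall of the transcript in transgenic kernels also stays open and untested. Transgene reads that were not assigned to Zm00001d047253 would leave SUS1 level if the native transcript and the assignment of its reads were unchanged. Neither was tested, so this stays open as well.

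Of the calls on deposited values, 15.1% were higher. A few genes taking most of the FPKM would lower all others, but the tables do not decide this: rescaled to the sum without the 20 most abundant genes 50.1% of the calls were higher, yet this rescaling also centres the median gene (0.016), which alone evens the split, and median-ratio rescaling, which does not single out these genes, gave 44.2%. The estimated depth of the libraries labelled transgenic was 1.16% higher. Only ratios close to 1 were searched, so a larger difference in library depth would have been missed and is not excluded. Whether the 20 genes were made in larger amounts in these kernels, or whether the other transcripts were fewer, stays open, since FPKM gives no absolute amount.

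The 3907 calls compare with a highest count of 2 in the 9 other splits of the 6 libraries, and with 0 in the 3 other splits that part every same-numbered pair. Each of those splits mixes the 2 labelled groups, so a group difference adds to its residual spread and lowers its count. Their counts therefore do not give the number of calls without a group difference. The real split was the only 1 to reach its count, and 10 splits are too few for a share under 0.05.

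Replicate 3 of both groups shared differences in very abundant genes. Zm00001d048851 had 35005, 35653 and 61930 FPKM in controls 1 to 3 and 31994, 34476 and 60908 FPKM in transgenic 1 to 3. Zm00001d048852 had 22034, 22798 and 13392 FPKM in controls 1 to 3 and 23136, 22634 and 14734 FPKM in transgenic 1 to 3. These 2 genes were chosen after their values were seen, and they lie within 10 ID numbers of each other. Replicate 3 over the mean of replicates 1 and 2 was 1.75 (control) and 1.83 (transgenic) for Zm00001d048851. For its neighbours it was lower: 0.597 and 0.644 for Zm00001d048852, 0.831 and 0.831 for Zm00001d048849, 0.814 and 0.698 for Zm00001d048848, and 0.91 and 0.891 for Zm00001d048847. Whether reads were divided differently among these neighbours was not tested. In 14 of the 20 most abundant genes, replicate 3 lay outside replicates 1 and 2 on the same side in both groups. Nearby ID numbers limit this count too, and it was not compared with chance.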
